A study of Homo sapiens with 12 samples.

How the data were processed

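Gene expression was measured by RNA sequencing in 12 libraries from HMLE cells, an immortalised human mammary epithelial line, in 4 groups of 3 biological replicates. HMLE-Twist cells express the transcription factor TWIST1 and serve as the model of cells after an epithelial to mesenchymal transition, and HMLE-pBp cells carry the control vector. Each line was given salinomycin, a potassium ionophore, at 0.2 uM for 24 hours, or DMSO as the mock. Per the labels, stranded mRNA libraries were made from 750 ng of RNA and sequenced in paired mode with 75 cycles per end.

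The authors deposited 4 tables, 1 per group, each with 26364 genes and 3 libraries. 26357 gene names were alike in all 4 tables, and 7 were not. The submitters' processing notes name DESeq2 (version string 1.1.0) and the genome build hg19, while the aligner, the counting program and the gene annotation are not given in the sources used here. The deposited tables of the mock groups hold FPKM (fragments per kilobase and library size), scaled by size factors set within the 3 libraries of each table alone. The deposited tables of the salinomycin groups are named FPKM but hold log2 values, which go below 0 and have the spread between the 3 libraries shrunk, again with size factors set within each table. The tables were therefore normalized separately and in different units, and could not be compared as they stand. The gene symbols were used as given. Since the build differs from that of the reference annotation (GRCh38, GENCODE release 29), no coordinates are given, and the reference served only for gene names and lengths.

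Whole reads were recovered for all 12 libraries. In the mock tables the values of a gene are whole multiples of 1 step, which gives its reads, and the step gives a gene length. Of 12903 genes with over 100 mock reads, 99.0% had a whole length at once and 121 took a multiple of their reads to reach one. Of 12274 of these genes with a reference length, 64.0% lay within 5% of it. Genes named below whose length lies farther from the reference are stated as such where their level matters. In the fold changes the length itself enters only through the pseudocount and the filter. A length short through a missed multiple would, however, mean mock reads too low by that multiple. The salinomycin fold change would then be too high in both lines. The difference of responses would change only through the pseudocount and the filter. The step predicted from the recovered reads over the step found was 1.0048 in HMLE-Twist and 1.0038 in HMLE-pBp. In the salinomycin tables the shrinkage was inverted with a penalised negative binomial model fitted to the values, and 98.2% (HMLE-Twist) and 95.9% (HMLE-pBp) of the values came within 0.1 of a whole read. For genes with a mean of over 10000 reads these shares were 67.4% and 54.0%. The largest distance from a whole read, for genes over 1000 reads, was 0.0522% and 0.0521% of the value. 612 genes, 313 of them with over 100 mock reads, were left out because the multiple of their reads was not settled. That exclusion uses lengths alone, with bounds of 95% of the longest coding sequence, 80% and 85% of the shortest transcript and 110% of the union of exons, and distances from the reference of 3.5% and 1.4%. It was tightened after fold changes of single genes had been seen, and the counts with no gene left out are given among the alternatives. List members lost this way are BUB1, CNIH1, COPG2, GALNT1, GALNT5, GINS2, MTHFD2, NDUFB5, NKD1, PGK1, PLK3, PSAP, SDF2L1, ST6GAL1, TIE1, TXN, UQCRFS1 and WARS, and IL8 is not in the tables under that name.

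FPKM was rebuilt from the recovered reads with median-of-ratios size factors over all 12 libraries and the recovered lengths. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries, whatever their group, were tested, which left 11882 of 25745 genes with settled reads. All 4 groups entered 1 limma fit (lmFit, then eBayes with a trend) on log2(FPKM + 1), with no covariate, and contrasts were tested at a Benjamini-Hochberg adjusted p under 0.05. Fold changes of genes near 0 in 1 group are understated by the added 1. The contrasts were salinomycin against mock in each line, the difference of these 2 responses, and HMLE-Twist against HMLE-pBp under mock and under salinomycin. The replicate numbers also carried structure, so the counts with the replicate number as a block are printed beside those without it. Before the data were examined, the test, the filter, the gene lists, the rule for naming genes and the alternatives were fixed, except those named here as added later.

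The 28 lists were ER chaperones and ATF6/XBP1 targets, ER-associated degradation, ATF4 and CHOP targets, COPII and ER-to-Golgi transport, COPI coat and Golgi structure, Golgi glycosylation enzymes, cholesterol biosynthesis, fatty acid synthesis, lysosome and autophagy, epithelial markers, mesenchymal markers, breast stem and progenitor markers, Wnt targets, G2/M and mitosis, G1/S and replication, p53 targets, hypoxia and glycolysis, iron, NRF2 targets, respiratory chain subunits, ion transport, NF-kB targets and cytokines, interferon-stimulated genes, cytosolic heat shock, luminal breast cells, leukocytes, endothelial cells, and common reference genes. They were tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry as alternatives. Beside the count of members past the threshold over all genes tested stands the count adjusted over the list alone. The lists do not state whether a high or a low level of a member, such as CD24, marks breast stem cells. Counts for breast stem and progenitor markers therefore show levels, not a gain or loss of stem character. Named genes follow a fixed rule: 11 genes always (1 of them is not reported here), the 6 largest rises and 6 largest falls past the threshold with a mean FPKM of at least 5 in the higher group and no overlap between the groups' libraries (no such condition for the difference of responses), and up to 3 members of each list past the threshold. Sex-linked marker genes were left out of the rule.

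The recovery and the fit were tested on simulated data made from the recovered reads. All salinomycin reads and 99.8% of mock values of genes with over 100 mock reads were recovered exactly, but 23 of 11798 tested genes were left at a fraction of their reads. The simulated salinomycin values were made with the same penalised model that the recovery inverts. Their recovery therefore does not test whether the authors' values have that form. Of 99 genes changed 1.5-fold in HMLE-Twist, 83.8% were called in the right direction, and of 98 changed 2-fold, 96.9% were, with 34 calls outside them. For the difference of responses the shares were 38.4% and 89.8%, with 6 calls outside, and 21 genes were called in HMLE-pBp with none changed. No fixed list was called with none planted, and a planted list of 25 genes had an adjusted p of 1.48e-51. The reads were drawn gene by gene with no replicate effect, so the simulation does not test list calls among correlated genes. Each gene had the median spread of genes of its level, and changes were planted only above a minimum of reads in HMLE-Twist. The shares and counts of gene calls therefore do not cover genes with a larger spread, or replicate effects, and may be too favourable for the real libraries. In the real libraries, splits other than the real one called up to 14 lists in each line.

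Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to TPM, size factors over the filtered genes, quantile normalization, the 6 libraries of a comparison alone, the replicate block, no trend, a fold change limit, an adjusted p under 0.01, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads, size factors set within each table, only genes with a length within 5% of the reference, a replicate block within each line, and no gene left out for an unsettled multiple. Errors are SE of the fitted log2 fold change or SD between 3 libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.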

Results

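RNA sequencing libraries were compared from 2 lines of human mammary epithelial cells, HMLE-Twist and HMLE-pBp, each after 24 hours with 0.2 uM salinomycin or with the mock, in 4 groups of 3 biological replicates. The recovered reads per library, in megareads, came to 21.09, 19.41 and 26.73 in HMLE-Twist mock, 22.16, 20.43 and 24.89 in HMLE-Twist salinomycin, 20.86, 17.91 and 24.71 in HMLE-pBp mock, and 21.62, 20.56 and 20.78 in HMLE-pBp salinomycin. Expression was tested for 11882 genes. The first principal component held 86.4% of the variance and separated the lines, and the second held 5.1% and separated salinomycin from mock in both. Below, log2 fold changes carry their SE from the limma fit and FPKM values carry the SD of 3 libraries. Medians of gene lists are medians of log2 fold changes, and each list's adjusted p comes from camera.

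The first question was which genes salinomycin changed in HMLE-Twist cells, the model of cells after an epithelial to mesenchymal transition. Genes of ER-to-Golgi transport, of the Golgi and of the amino acid stress response rose together, and genes of cholesterol synthesis and of cell division fell. As lists they lost the call at adjusted p = 0.137 with an estimated correlation for both transport and Golgi lists, and 0.265 for the others. RCN3, a calcium-binding protein of the ER lumen, rose most, from 1.88 ± 0.541 to 26.0 ± 1.27 FPKM (SD, n = 3), a log2 fold change of 3.25 ± 0.12 (adjusted p = 5.53e-08). KDELR3, a receptor that returns escaped proteins from the Golgi to the ER, rose from 25.2 ± 2.77 to 147 ± 8.12 FPKM, by 2.51 ± 0.13 (adjusted p = 4.25e-07). PYCR1, which makes proline, rose by 2.22 ± 0.19, INHBE, an activin subunit, by 2.19 ± 0.20, CPZ, a carboxypeptidase, by 2.11 ± 0.09, and IER3 by 2.07 ± 0.21. HSPA5, the main chaperone of the ER lumen, rose from 349 ± 33.7 to 493 ± 25 FPKM, by 0.50 ± 0.11 (adjusted p = 0.0055), and was higher in all 3 treated libraries than in any mock library. DDIT3, which encodes the stress transcription factor CHOP, rose by 1.03 ± 0.35 (adjusted p = 0.0462). Its adjusted p ran from 0.0352 to 0.151 over the alternatives, the last of these without mock replicate 1 of the line.

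The 6 largest falls in HMLE-Twist were MEST at -2.07 ± 0.21, TMEM64 at -1.7 ± 0.15, WISP1, a secreted matricellular protein, at -1.7 ± 0.19, PLAC8 at -1.64 ± 0.10, COL3A1, a fibrillar collagen chain, at -1.61 ± 0.30, and MAP2K6, a kinase upstream of p38, at -1.50 ± 0.23. COL3A1 fell from 477 ± 146 to 162 ± 68.5 FPKM (adjusted p = 0.00213). HMGCS1, an early enzyme of cholesterol synthesis, fell from 53.9 ± 16.3 to 27.8 ± 1.51 FPKM, by 0.88 ± 0.19 on the log2 scale (adjusted p = 0.00554). Among the markers of the transition, FN1 (fibronectin) rose by 0.61 ± 0.09 (adjusted p = 3.94e-04). TWIST1 (0.42 ± 0.26), VIM (0.33 ± 0.22), ZEB1 (-0.28 ± 0.13), CDH2 (0.02 ± 0.10), ESRP1 (-0.08 ± 0.08) and CDH1 (0.00 ± 0.08) did not pass. CDH1 and ESRP1 lay at 0.0598 ± 0.0337 and 0.0720 ± 0.0413 FPKM in the mock libraries of this line, too low to show a fall. The recovered length was 5.57 times the reference for IER3, 1.55 for HMGCS1, 0.61 for PLAC8 and 0.14 for MAP2K6, which bears on their FPKM levels. For PLAC8 and MAP2K6 a missed multiple, if there was one, would make the fall appear too small.

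Lists of the secretory pathway rose in HMLE-Twist. Of 38 genes of COPII and ER-to-Golgi transport, 30 rose and 1 fell (31 and 2 adjusted over the list alone), with a median of 0.64 and an adjusted p of 2.46e-16, against adjusted p = 0.137 with an estimated correlation. KDELR3, the membrane protein YIF1A (1.74 ± 0.15) and the coat subunit SEC24D (1.32 ± 0.15) led it. Among 41 genes of the COPI coat and Golgi structure, 30 rose and 3 fell (31 and 3 adjusted over the list alone), with a median of 0.62 and adjusted p = 3.22e-14, or adjusted p = 0.137 with an estimated correlation. The golgin GOLGA3 rose by 1.51 ± 0.07, the GTPase ARF4 by 1.43 ± 0.16 and ARFGAP1, which acts on the related GTPase ARF1, by 1.42 ± 0.14. The 23 ER chaperones and ATF6/XBP1 targets had 9 that rose and none that fell (10 adjusted over the list alone), with a median of 0.22 and adjusted p = 1.4e-05, or adjusted p = 0.265 with an estimated correlation. HERPUD1, whose recovered length was 0.65 of the reference, rose by 1.64 ± 0.13, the protein disulfide isomerase P4HB by 0.94 ± 0.11 and the transcription factor XBP1 by 0.91 ± 0.13. In ER-associated degradation 7 of 21 genes rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.25 and adjusted p = 0.0174, or adjusted p = 0.291 with an estimated correlation. It was led by the ubiquitin ligase SYVN1 (1.30 ± 0.13) and ERLEC1 (0.99 ± 0.09). Golgi glycosylation enzymes had 9 of 36 that rose and 2 that fell (9 and 2 adjusted over the list alone), with a median of 0.09 and adjusted p = 0.0238, or adjusted p = 0.493 with an estimated correlation. GALNT3 (1.26 ± 0.13), SLC35A2 (1.25 ± 0.15) and B4GALT5 (1.1 ± 0.11) were the largest. Over the camera alternatives the list's adjusted p ran from 0.013 to 0.0755, the last with only genes near their reference length.

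Stress, lysosome, iron and cytokine lists also rose in HMLE-Twist. Of 28 ATF4 and CHOP targets, the genes of the integrated stress response, 23 rose and none fell (26 adjusted over the list alone), with a median of 0.97 and adjusted p = 2.57e-11, or adjusted p = 0.265 with an estimated correlation. PPP1R15A, a phosphatase subunit that ends the response, rose by 1.71 ± 0.32, and the amino acid enzymes CBS and ASNS by 1.5 ± 0.28 and 1.49 ± 0.26. Of 16 NF-kB targets and cytokines 11 rose and none fell (13 adjusted over the list alone), with a median of 1.25 and adjusted p = 9.04e-08, or adjusted p = 0.265 with an estimated correlation. The chemokines CXCL8 and CXCL1 rose by 2.06 ± 0.34 and 1.99 ± 0.46, and NFKB2 by 1.71 ± 0.15. Lysosome and autophagy genes had 10 of 33 that rose and 2 that fell (11 and 2 adjusted over the list alone), with a median of 0.18 and adjusted p = 0.000483, or adjusted p = 0.265 with an estimated correlation, and included the autophagy receptor SQSTM1 (1.56 ± 0.16) and WIPI1 (1.44 ± 0.12). In the iron list 8 of 16 genes rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.32 and adjusted p = 0.0174, or adjusted p = 0.265 with an estimated correlation. The ferritin light chain FTL rose by 0.94 ± 0.19 and the transferrin receptor TFRC by 0.85 ± 0.15, and the list's adjusted p ran from 0.00975 to 0.0646, the last without mock replicate 3 of the line.

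Lists of lipid synthesis, growth, respiration and heat shock fell in HMLE-Twist. Of 25 cholesterol biosynthesis genes 17 fell and none rose (18 adjusted over the list alone), with a median of -0.55 and adjusted p = 4.55e-07, or adjusted p = 0.265 with an estimated correlation. INSIG1, which holds back sterol synthesis, stood at -1.14 ± 0.26, the mevalonate kinase MVK at -1.1 ± 0.13 and the isomerase IDI1 at -1.06 ± 0.13. Fatty acid synthesis had 9 of 14 genes that fell and none that rose (9 fell and 1 rose adjusted over the list alone), with a median of -0.48 and adjusted p = 0.00182, or adjusted p = 0.265 with an estimated correlation, among them the desaturase SCD (-1.04 ± 0.10) and LPIN1 (-0.72 ± 0.09). In G2/M and mitosis 14 of 23 genes fell (18 adjusted over the list alone), with a median of -0.34 and adjusted p = 1.26e-06, or adjusted p = 0.265 with an estimated correlation, and the kinase CDK1, with a recovered length 1.73 times the reference, stood at -0.71 ± 0.11. In G1/S and replication 11 of 25 fell (13 adjusted over the list alone), with a median of -0.20 and adjusted p = 5.4e-05, or adjusted p = 0.265 with an estimated correlation. It was led by the cyclin CCNE2 (-0.75 ± 0.09). Cytosolic heat shock genes had 7 of 16 that fell (9 adjusted over the list alone), with a median of -0.38 and adjusted p = 0.000159, or adjusted p = 0.265 with an estimated correlation, and HSP90AA1 stood at -0.75 ± 0.13. Of 31 respiratory chain subunits 10 fell (10 adjusted over the list alone), with a median of -0.15 and adjusted p = 0.00115, or adjusted p = 0.269 with an estimated correlation, with ATP5C1 at -0.55 ± 0.10 and NDUFV2 at -0.47 ± 0.07. The remaining 13 lists did not pass with camera in HMLE-Twist. Mesenchymal markers split, with 10 of 41 that rose and 10 that fell (adjusted p = 0.904), among them LOX, which cross-links collagen, at 1.62 ± 0.11 and LUM at -1.05 ± 0.14, with a recovered length 0.7 of the reference. Of 44 epithelial markers 4 rose and 2 fell (adjusted p = 0.899), with the laminin chain LAMB3 at 1.73 ± 0.15. The adjusted p was 0.0699 for ion transport and 0.0865 for breast stem and progenitor markers. Among the camera alternatives, ion transport passed with the block within each line (0.0438), a pseudocount of 0.1 (0.0399), TPM (0.0474) and reference lengths (0.0478). It also passed without mock replicate 1 (0.0221) or salinomycin replicate 2 (0.0343), within 0.0221 to 0.197. The stem list passed among them with a pseudocount of 0.1 (0.0399), a mean FPKM of at least 5 (0.0337) and reference lengths (0.0418). It also passed without salinomycin replicate 2 (0.0449), within 0.0337 to 0.125. The adjusted p was 0.125 for endothelial cells, 0.206 for interferon-stimulated genes, 0.31 for leukocytes, 0.418 for p53 targets, hypoxia and glycolysis, NRF2 targets and luminal breast cells, 0.572 for Wnt targets and 0.854 for reference genes.

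In all, 3130 genes changed in HMLE-Twist, 1520 up and 1610 down, and 186 of the rises and 45 of the falls were at least 2-fold. With the replicate number as a block 4455 genes passed, among them 3129 of the 3130. No list passed with an estimated correlation between its genes, while fry passed 21.

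**Figure D1:**
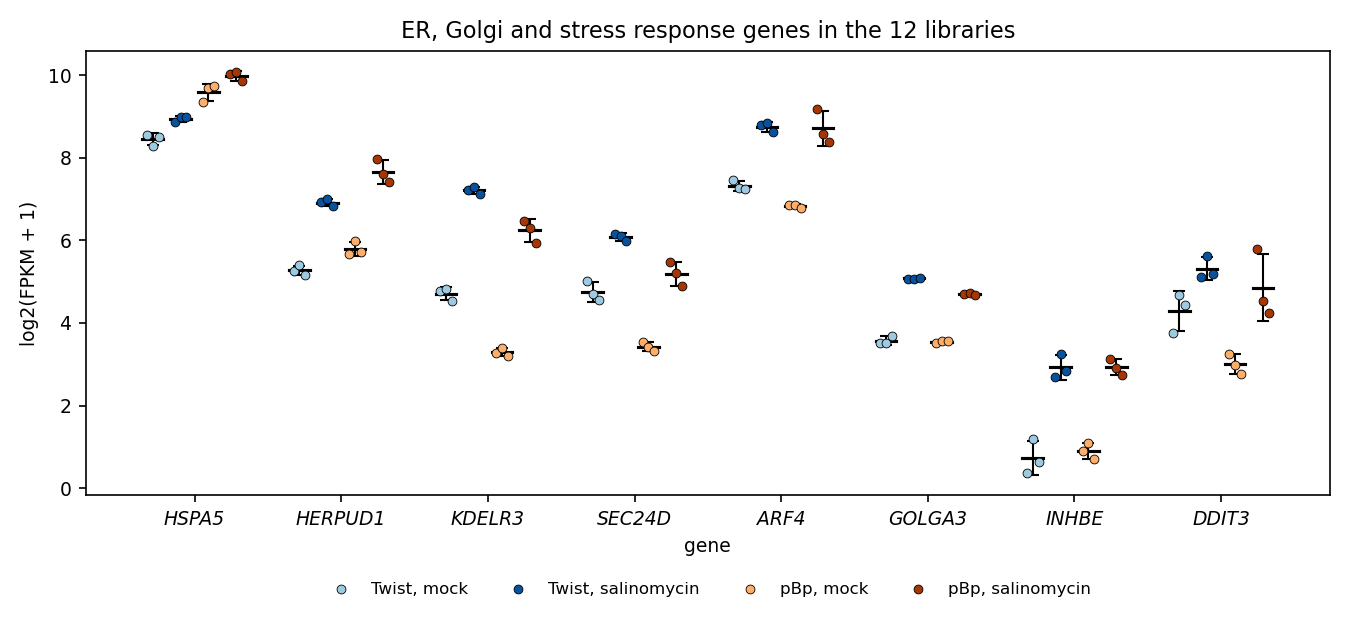
Levels of 8 ER, Golgi and stress response genes as log2(FPKM + 1) in each of the 12 libraries, with points for libraries, bars for the group mean and error bars for the SD (n = 3). KDELR3 rose by 2.51 in HMLE-Twist and 2.95 in HMLE-pBp, while HSPA5 rose by 0.50 and 0.40.

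The same question in HMLE-pBp cells, which keep their epithelial form, gave rises in cholesterol synthesis beside those of the Golgi and the stress response. As lists these lost the call at adjusted p = 0.0908, 0.101 and 0.284 with an estimated correlation. KDELR3 rose most, from 8.79 ± 0.658 to 75.5 ± 13.8 FPKM (SD, n = 3), by 2.95 ± 0.13 (adjusted p = 3.16e-07). ACSS2, which makes acetyl-CoA for lipid synthesis, rose from 6.61 ± 0.206 to 53.2 ± 11.2 FPKM, by 2.81 ± 0.14 (adjusted p = 5.97e-07), and HMGCS1 from 22.4 ± 3.98 to 98.5 ± 7.50 FPKM, by 2.10 ± 0.19 (adjusted p = 5.42e-05). INHBE rose by 2.03 ± 0.20, ARF4 by 1.88 ± 0.16 and HERPUD1 by 1.87 ± 0.13. DDIT3 rose by 1.86 ± 0.35 (adjusted p = 0.004), ESRP1, an epithelial splicing regulator, by 0.51 ± 0.08 (adjusted p = 0.00119), and HSPA5 by 0.40 ± 0.11 (adjusted p = 0.0265). The largest falls were the small nucleolar RNA SNORA24 at -1.64 ± 0.25, SNHG4, a host gene of such RNAs, at -1.53 ± 0.22, the water and glycerol channel AQP3 at -1.48 ± 0.13, the sterol exporter ABCG1 at -1.37 ± 0.16, SNORA26 at -1.36 ± 0.33 and the amino acid transporter SLC7A2 at -1.33 ± 0.19. SNHG4 had a recovered length 2.28 times the reference. AQP3 fell from 86.3 ± 12.6 to 30.4 ± 5.03 FPKM (adjusted p = 3.54e-05). CDH2 fell by 0.35 ± 0.10 (adjusted p = 0.0333). VIM (0.52 ± 0.22, adjusted p = 0.11), TWIST1 (-0.17 ± 0.26), FN1 (-0.13 ± 0.09), CDH1 (0.10 ± 0.08) and ZEB1 (0.09 ± 0.13) did not pass. Calls that ended without 1 library, each with the range of its adjusted p over the alternatives, were HSPA5 without salinomycin replicate 2 (0.0202 to 0.0879), CDH2 without mock replicate 3 (0.0202 to 0.141) and SNORA26 without salinomycin replicate 1 (0.00401 to 0.0659).

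Cholesterol biosynthesis was the list with the smallest p in HMLE-pBp. Of its 25 genes 23 rose and none fell (23 adjusted over the list alone), with a median of 0.97 and adjusted p = 5.78e-21, or adjusted p = 0.0908 with an estimated correlation. ACAT2 rose by 1.64 ± 0.11 and the decarboxylase MVD by 1.63 ± 0.22. In fatty acid synthesis 8 of 14 genes rose and none fell (8 adjusted over the list alone), with a median of 0.57 and adjusted p = 1.04e-05, or adjusted p = 0.217 with an estimated correlation, among them the desaturase FADS2 (1.21 ± 0.16) and ACLY (1.08 ± 0.07). Of 41 genes of the COPI coat and Golgi structure 27 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 0.58 and adjusted p = 6e-16, or adjusted p = 0.101 with an estimated correlation. The coat subunit COPA rose by 1.30 ± 0.13 and ARFGAP3 by 1.27 ± 0.10. COPII and ER-to-Golgi transport had 23 of 38 genes that rose and 1 that fell (27 and 2 adjusted over the list alone), with a median of 0.52 and adjusted p = 1.74e-12, or adjusted p = 0.172 with an estimated correlation, among them SEC24D (1.77 ± 0.15) and SEC24A (1.13 ± 0.15). Of 28 ATF4 and CHOP targets 20 rose and none fell (22 and 1 adjusted over the list alone), with a median of 0.98 and adjusted p = 1.52e-10, or adjusted p = 0.284 with an estimated correlation, with the enzymes CBS and CTH both at 1.5 (SE 0.28 and 0.25). Among 23 ER chaperones and ATF6/XBP1 targets 8 rose and none fell (9 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.00137, or adjusted p = 0.432 with an estimated correlation, led after HERPUD1 by XBP1 (0.89 ± 0.13). Hypoxia and glycolysis had 13 of 27 genes that rose and none that fell (17 adjusted over the list alone), with a median of 0.41 and adjusted p = 9.34e-08, or adjusted p = 0.284 with an estimated correlation. The glucose transporter SLC2A3 rose by 1.60 ± 0.13 and the glycolytic enzymes ALDOC and ENO2 by 1.51 ± 0.14 and 1.1 ± 0.14.

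Other lists fell in HMLE-pBp. Of 25 genes of G1/S and replication 12 fell (14 adjusted over the list alone), with a median of -0.25 and adjusted p = 4.36e-05, or adjusted p = 0.284 with an estimated correlation. It was led by the cyclin CCNE1 (-0.63 ± 0.13). Cytosolic heat shock genes had 7 of 16 that fell and 1 that rose (11 and 1 adjusted over the list alone), with a median of -0.52 and adjusted p = 0.0021, or adjusted p = 0.432 with an estimated correlation, among them HSPE1 (-0.70 ± 0.10) and HSP90AA1 (-0.65 ± 0.13). Among 12 Wnt targets 4 fell (5 adjusted over the list alone), with a median of -0.41 and adjusted p = 0.00202, or adjusted p = 0.284 with an estimated correlation, and the Wnt inhibitor DKK1 stood at -1.01 ± 0.20. Golgi glycosylation enzymes had 8 of 36 that fell and 1 that rose (9 and 1 adjusted over the list alone), with a median of -0.16 and adjusted p = 0.0133, or adjusted p = 0.533 with an estimated correlation. Its member that rose was the sugar transporter SLC35A2 (0.67 ± 0.15), and the list's adjusted p ran from 0.0011 to 0.0689, the last without salinomycin replicate 1. Breast stem and progenitor markers had 4 of 11 that fell (4 adjusted over the list alone), with a median of -0.17 and adjusted p = 0.0432, or adjusted p = 0.275 with an estimated correlation, and PROCR stood at -1.02 ± 0.16. In G2/M and mitosis 3 of 23 fell (1 adjusted over the list alone), with a median of -0.12 and adjusted p = 0.0264, or adjusted p = 0.596 with an estimated correlation, with CDC20 at -0.37 ± 0.08. Of 16 NF-kB targets 1 rose (0 adjusted over the list alone), NFKB2 at 0.52 ± 0.15, with a list median of 0.33 and adjusted p = 0.0258, or adjusted p = 0.596 with an estimated correlation. These 3 calls ended without several single libraries: the stem list without mock replicate 1 (adjusted p = 0.064) and salinomycin replicates 1 (0.0689) and 2 (0.0549), G2/M without mock replicates 1 (0.0541) and 2 (0.0669) and salinomycin replicate 1 (0.152), and NF-kB without mock replicate 2 (0.0966) and salinomycin replicate 1 (0.762). With all libraries kept, the stem list ended with a pseudocount of 0.1 (0.0559), a mean FPKM of at least 5 (0.139) and reference lengths (0.223). G2/M ended with quantile normalization (0.071), and NF-kB with a pseudocount of 0.1 (0.0559), a mean FPKM of at least 5 (0.0899) and reference lengths (0.0589). Over the camera alternatives their adjusted p ran from 0.023 to 0.223, from 0.00204 to 0.152 and from 0.00018 to 0.762. NFKB2 itself had an adjusted p of 0.116 without salinomycin replicate 1 (0.0106 to 0.116 over the alternatives).

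Of the other 14 lists none passed with camera in HMLE-pBp with all libraries kept. Interferon-stimulated genes (adjusted p = 0.0743) passed without mock replicate 3 (0.0209) and without salinomycin replicate 1 (0.0477), within 0.0209 to 0.737, and NRF2 targets (adjusted p = 0.0947) without mock replicate 1 (0.04), within 0.04 to 0.969. Of 44 epithelial markers 1 rose and 6 fell (adjusted p = 0.0947), and of 41 mesenchymal markers 4 rose and 4 fell (adjusted p = 0.958), with LOX at 1.77 ± 0.11. ER-associated degradation had 4 of 21 that rose and 4 that fell (adjusted p = 0.493). In all, 2227 genes changed, 1125 up and 1102 down, and 100 of the rises and 43 of the falls were at least 2-fold. With the replicate number as a block 3951 genes passed, all 2227 among them. The count fell to 1309 without mock replicate 2, 1114 without mock replicate 3 and 1194 without salinomycin replicate 1 of this line. With an estimated correlation no list passed. Fry passed 15 lists against the 14 of camera, so at least 1 list that camera did not call passed with fry. Which of the camera calls fry kept is not given here.

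**Figure D2:**
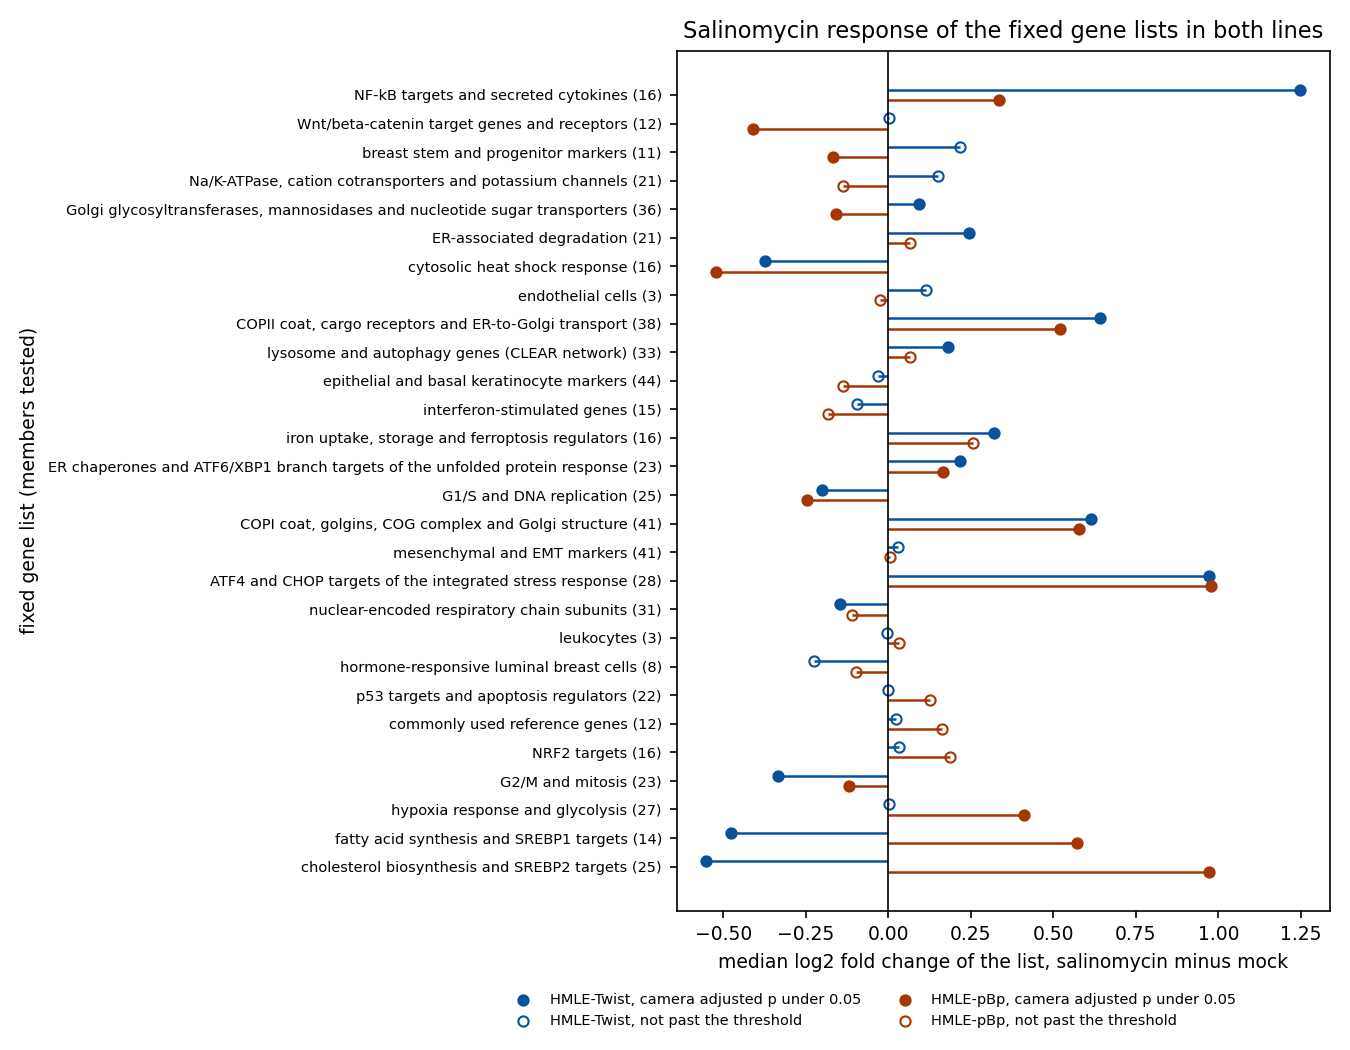
Median log2 fold change after salinomycin of each of the 28 gene lists in HMLE-Twist and HMLE-pBp, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points for lists not past it. Cholesterol biosynthesis stood at -0.55 in HMLE-Twist and 0.97 in HMLE-pBp, while COPII transport stood at 0.64 and 0.52.

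The responses of the lines were then compared directly, as the response of HMLE-Twist minus that of HMLE-pBp. Sterol and fatty acid synthesis moved in opposite directions, and as lists lost the call at adjusted p = 0.0621 and 0.117 with an estimated correlation. ACSS2 differed most, by -3.30 ± 0.19 (adjusted p = 5.25e-06), going from 17.2 ± 2 to 12.0 ± 1.37 FPKM in HMLE-Twist (SD, n = 3) against its rise in HMLE-pBp. HMGCS1 differed by -2.98 ± 0.27 (adjusted p = 1.03e-04), INSIG1 by -2.66 ± 0.36, ACAT2 by -2.51 ± 0.16, IDI1 by -2.41 ± 0.18 and the glycolytic enzyme ALDOC by -2.27 ± 0.19. RCN3 differed by 2.94 ± 0.17 (adjusted p = 5.25e-06), but in HMLE-pBp it went from 0.0267 ± 0.0244 to 0.266 ± 0.0203 FPKM, so that the added 1 sets much of this value. On the same side CXCL1 differed by 2.43 ± 0.65 (adjusted p = 0.03), IER3 by 2.41 ± 0.30, the transporter SLCO4A1 by 2.20 ± 0.30, MYC by 2.11 ± 0.20 and the phosphatase DUSP4 by 2.02 ± 0.22. MYC rose from 20.4 ± 2.57 to 63.1 ± 8.59 FPKM in HMLE-Twist and went from 141 ± 21.8 to 97.0 ± 11 FPKM in HMLE-pBp. FN1 (0.74 ± 0.12, adjusted p = 0.00334) and ESRP1 (-0.59 ± 0.11, adjusted p = 0.0064) also differed. ESRP1 was near 0 in HMLE-Twist, where the added 1 holds its response near 0, so that the value restates its rise in HMLE-pBp. HSPA5 (0.10 ± 0.15), DDIT3 (-0.83 ± 0.49), TWIST1 (0.58 ± 0.36), CDH1 (-0.10 ± 0.11), CDH2 (0.37 ± 0.14), VIM (-0.19 ± 0.31) and ZEB1 (-0.36 ± 0.18) did not pass. Without salinomycin replicate 1 of HMLE-Twist the call of CXCL1 ended (adjusted p 0.00208 to 0.0784 over the alternatives). The recovered lengths of ACAT2 and IDI1 were 0.60 and 0.57 of the reference.

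**Figure D3:**
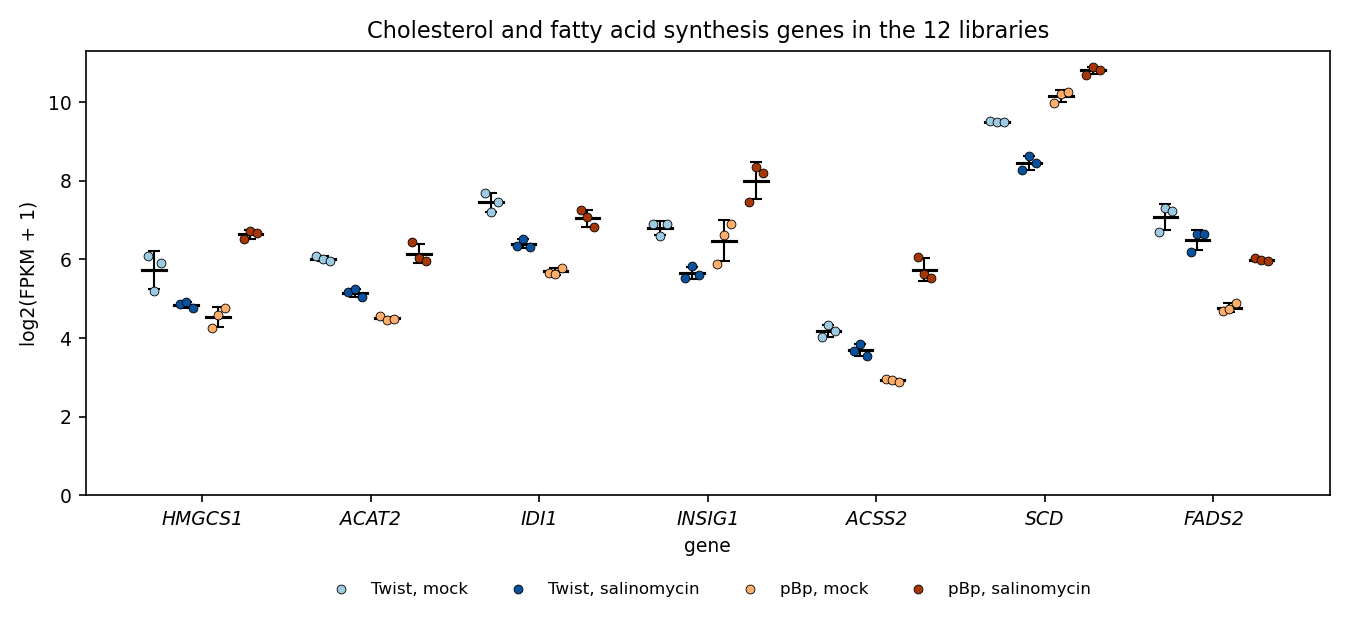
Levels of 7 genes of cholesterol and fatty acid synthesis as log2(FPKM + 1) in each of the 12 libraries, with points for libraries, bars for the group mean and error bars for the SD (n = 3). HMGCS1 fell by 0.88 in HMLE-Twist and rose by 2.10 in HMLE-pBp.

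Of the 28 lists 9 passed for the difference of responses. All of them lost the call with an estimated correlation, which is given beside each. Of 25 cholesterol biosynthesis genes 22 differed, all lower in HMLE-Twist (23 adjusted over the list alone), with a median of -1.62 and adjusted p = 7.23e-24, or adjusted p = 0.0621 with an estimated correlation. In fatty acid synthesis 7 of 14 differed, again lower in HMLE-Twist (8 adjusted over the list alone), with a median of -0.73 and adjusted p = 9.1e-08, or adjusted p = 0.117 with an estimated correlation, FADS2 by -1.79 ± 0.22 and SCD by -1.69 ± 0.14. Golgi glycosylation had 9 of 36 with the higher response in HMLE-Twist (13 higher and 1 lower adjusted over the list alone), with a median of 0.29 and adjusted p = 5.44e-05, or adjusted p = 0.547 with an estimated correlation. B4GALT5 differed by 1.02 ± 0.15, GALNT3 by 0.96 ± 0.18 and the sialyltransferase ST3GAL1 by 0.86 ± 0.16. Of 16 NF-kB targets 7 had the higher response in HMLE-Twist (9 adjusted over the list alone), with a median of 0.90 and adjusted p = 0.000758, or adjusted p = 0.547 with an estimated correlation, CXCL8 by 2.09 ± 0.48. Hypoxia and glycolysis had 9 of 27 lower in HMLE-Twist (13 lower and 3 higher adjusted over the list alone), with a median of -0.41 and adjusted p = 0.00149, or adjusted p = 0.547 with an estimated correlation. PFKFB4 differed by -0.95 ± 0.22 and BNIP3, whose recovered length was 0.57 of the reference, by -0.99 ± 0.18, and the list's adjusted p ran from 9e-06 to 0.0517, the last with only genes near their reference length. Breast stem and progenitor markers had 4 of 11 higher (4 adjusted over the list alone), with a median of 0.45 and adjusted p = 0.00249, or adjusted p = 0.114 with an estimated correlation. Its members were led by MYC and by PROCR (0.90 ± 0.22), whose adjusted p ran from 0.00102 to 0.0606, the last without HMLE-pBp mock replicate 3. Among 12 Wnt targets 2 were higher (3 adjusted over the list alone), with a median of 0.36 and adjusted p = 0.0078, or adjusted p = 0.547 with an estimated correlation, MYC and the cyclin CCND1 (1.22 ± 0.33). CCND1 had an adjusted p of 0.0782 without HMLE-Twist salinomycin replicate 3 (0.00613 to 0.0782 over the alternatives). In G2/M and mitosis 4 of 23 were lower (4 adjusted over the list alone), with a median of -0.25. The list had adjusted p = 0.0123, or adjusted p = 0.669 with an estimated correlation. Without HMLE-pBp salinomycin replicate 2 the adjusted p was 0.0662 (0.00063 to 0.0662 over the camera alternatives). Ion transport had 3 of 21 higher and 2 lower (7 and 2 adjusted over the list alone), with a median of 0.26 and adjusted p = 0.0432, or adjusted p = 0.547 with an estimated correlation. The taurine transporter SLC6A6 differed by 1.70 ± 0.26 and the potassium channel KCNN4 by 1.15 ± 0.26. This call ended without any 1 of 6 libraries, HMLE-Twist mock replicates 2 (0.0981) and 3 (0.115), its salinomycin replicate 1 (0.0668), HMLE-pBp mock replicates 2 (0.0559) and 3 (0.0557) and its salinomycin replicate 3 (0.0924). The list's adjusted p ran from 0.0141 to 0.115 over the camera alternatives.

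The COPII, COPI and Golgi, ATF4 and CHOP, and ER chaperone lists did not pass for a difference. The adjusted p was 0.115 for COPII transport (median 0.05), 0.977 for COPI and Golgi structure, 0.773 for ATF4 and CHOP targets (median 0.01) and 0.249 for ER chaperones (median 0.05). COPII transport passed with quantile normalization (0.04) and without HMLE-Twist mock replicate 1 (0.0141) or HMLE-pBp salinomycin replicate 1 (0.0157), ATF4 and CHOP targets without HMLE-Twist mock replicate 2 (0.0452), and ER chaperones without HMLE-pBp mock replicate 1 (0.0357). Their adjusted p over the camera alternatives ran from 0.0141 to 0.612, from 0.0452 to 0.998 and from 0.0357 to 0.557. ER-associated degradation had 3 of 21 genes with the higher response in HMLE-Twist and an adjusted p of 0.0513 (0.02 to 0.14 over the camera alternatives). Among these alternatives it passed rescaled to TPM (0.0443) and with quantile normalization (0.0342). It also passed without HMLE-Twist mock replicate 1 (0.0205), its salinomycin replicate 2 (0.0384), HMLE-pBp mock replicate 1 (0.02) or its salinomycin replicates 1 (0.0441) and 2 (0.0328). Respiratory chain subunits (0.115) passed without HMLE-Twist mock replicate 1 (0.00634), within 0.00634 to 0.502. Of the 850 genes that changed in both lines, 711 went the same way, 468 up and 243 down, where 143.9 and 149.3 would be shared by chance (Fisher's exact test across genes, p = 6.28e-148 and 4.87e-16; genes are not independent replicates). The other 139 went opposite ways. Each of them also passed for the difference, which follows from opposite calls in 1 fit and is no separate test. Mock reads left at a fraction would give a false rise in both lines, so chance alone is not the full baseline for shared rises. Among 7500 genes near their reference length, 315 rises were shared, where 98.3 would be by chance. Across genes the log2 fold changes of the lines had a Pearson r of 0.256 and a Spearman rho of 0.206. In all, the response of 1622 genes differed, 830 higher and 792 lower in HMLE-Twist, and 172 and 78 of these by at least 2-fold. Rescaled to TPM the count was 1359, 864 higher and 495 lower, and with the replicate number as a block it was 3460, with all 1622 among them. Without 1 library it was 874 (HMLE-Twist mock replicate 2), 797 and 799 (its salinomycin replicates 1 and 3), 893 and 772 (HMLE-pBp mock replicates 2 and 3) or 1069 (its salinomycin replicate 2).

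The lines themselves were compared under mock, to show how far the transition had gone. The level of TWIST1 cannot show this, since its expression defines HMLE-Twist. TWIST1 stood at 719 ± 340 FPKM in HMLE-Twist and 2.52 ± 0.0359 FPKM in HMLE-pBp (SD, n = 3), a log2 difference of 7.58 ± 0.26 (adjusted p = 6.56e-11). CDH1, the epithelial cadherin, stood at 0.0598 ± 0.0337 against 169 ± 5.62 FPKM, a difference of -7.32 ± 0.08 (adjusted p = 1.32e-14). VIM (vimentin) was higher by 5.44 ± 0.22, the repressor ZEB1 by 4.55 ± 0.13, CDH2 (neural cadherin) by 2.11 ± 0.10 and FN1 by 1.69 ± 0.09, while ESRP1 was lower (-5.01 ± 0.08). The largest differences toward HMLE-Twist were COL3A1 at 8.81 ± 0.30 and TWIST1, then the proteoglycan DCN at 7.38 ± 0.10 (recovered length 0.34 of the reference), COL6A2 at 7.29 ± 0.26, COL1A1 at 7.25 ± 0.17 and COL1A2 at 6.79 ± 0.15. Toward HMLE-pBp they were the keratins KRT6A at -9 ± 0.23, KRT17 at -8.79 ± 0.12, KRT14 at -8.53 ± 0.16 and KRT5 at -8.23 ± 0.19, the protease inhibitor SPINT2 at -8.60 ± 0.09 and the hemidesmosome collagen COL17A1 at -8.32 ± 0.14. HSPA5 (-1.14 ± 0.11) was lower in HMLE-Twist, and DDIT3 (1.29 ± 0.35) and HMGCS1 (1.2 ± 0.19) were higher. All 10 of the genes named in every comparison passed here.

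**Figure D4:**
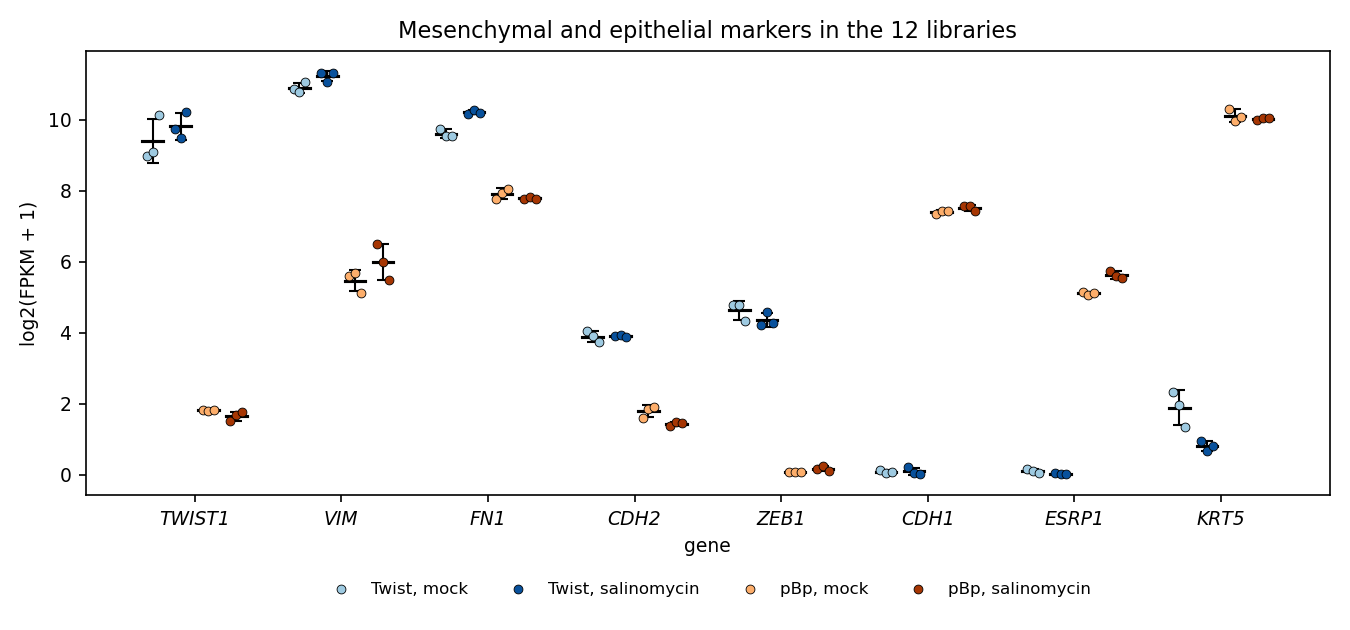
Levels of 8 mesenchymal and epithelial markers as log2(FPKM + 1) in each of the 12 libraries, with points for libraries, bars for the group mean and error bars for the SD (n = 3). TWIST1, VIM and ZEB1 were high in all 6 HMLE-Twist libraries, and CDH1, ESRP1 and KRT5 in all 6 HMLE-pBp libraries, with or without salinomycin.

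Of 44 epithelial markers all 44 were lower in HMLE-Twist (44 adjusted over the list alone), with a median of -5.10 and adjusted p = 4.06e-24. This call held with the estimated correlation, where the adjusted p was 0.00142, and it alone did. Among 41 mesenchymal markers 33 were higher and 4 lower (33 and 4 adjusted over the list alone), with a median of 2.83 and adjusted p = 5.98e-10, or adjusted p = 0.0966 with an estimated correlation. Golgi glycosylation enzymes had 29 of 36 lower and 2 higher (29 and 2 adjusted over the list alone), with a median of -1.24 and adjusted p = 3.51e-06, or adjusted p = 0.522 with an estimated correlation. GALNT3 (-5.74 ± 0.13) was lower and the mannosidase MAN1A1 (3.91 ± 0.09) higher. Of 23 ER chaperones and ATF6/XBP1 targets 21 were lower and 1 higher (21 and 1 adjusted over the list alone), with a median of -0.95 and adjusted p = 3.12e-05, or adjusted p = 0.522 with an estimated correlation, among them HYOU1 (-1.64 ± 0.12) and calnexin, CANX (-1.51 ± 0.10). Breast stem and progenitor markers had 9 of 11 lower and 2 higher (9 and 2 adjusted over the list alone), with a median of -2.27. The list had adjusted p = 0.00249, or adjusted p = 0.0966 with an estimated correlation. CD24 stood at -7.31 ± 0.14 and ALDH1A3 at -5.32 ± 0.08. These counts show levels, not a loss of stem character. In G1/S and replication 17 of 25 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.42 and adjusted p = 0.00336, or adjusted p = 0.612 with an estimated correlation, with CCNE2 at 1.24 ± 0.09 and TYMS, which makes thymidylate, at 1.14 ± 0.07. Of 21 ion transport genes 16 were lower and 3 higher (16 and 3 adjusted over the list alone), with a median of -0.83 and adjusted p = 0.00928, or adjusted p = 0.522 with an estimated correlation, with the potassium channels KCNK1 at -4.70 ± 0.08 and KCNK2 at 3.55 ± 0.12. NF-kB targets had 10 of 16 lower and 1 higher (10 and 1 adjusted over the list alone), with a median of -1.29 and adjusted p = 0.0277, or adjusted p = 0.778 with an estimated correlation, with the cytokine IL1A at -4.70 ± 0.27 (recovered length 1.38 times the reference). ER-associated degradation had 15 of 21 lower and 4 higher (15 and 4 adjusted over the list alone), with a median of -0.51 and adjusted p = 0.0452, or adjusted p = 0.612 with an estimated correlation, with DERL1 at -2.21 ± 0.10. The last call ended with the replicate block (0.0528), TPM (0.0503) and reference lengths (0.0823). It also ended without HMLE-Twist mock replicate 2 (0.0598), HMLE-pBp mock replicate 2 (0.0553) or HMLE-pBp salinomycin replicate 1 (0.0549), within a range of 0.0212 to 0.0823. That of NF-kB ended with a mean FPKM of at least 5 (0.2), reference lengths (0.109), and without HMLE-pBp mock replicate 1 (0.0557), with an adjusted p of up to 0.2. With only genes near their reference length the stem and progenitor call ended as well (0.0823, within 0.000786 to 0.0823).

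Single markers of other cell types differed between the lines in both directions, as did 8719 of all 11882 genes tested. Their lists did not pass in the main fit. Of 8 markers of luminal breast cells 6 were lower and 2 higher in HMLE-Twist (adjusted p = 0.197, or 0.0142 with a mean FPKM of at least 5, within 0.0142 to 0.438), among them KRT18 (-3.69 ± 0.10) and KRT8 (-3.62 ± 0.21), which the epithelial list holds too. The 3 leukocyte markers tested were CD14 (-3.41 ± 0.27), CSF1R (-1.60 ± 0.08) and CD68 (1.07 ± 0.08), and the 3 endothelial markers were ROBO4 (1.08 ± 0.11), KDR (0.82 ± 0.13) and ENG (-0.80 ± 0.15), with an adjusted p of 0.574 for both lists. Cholesterol biosynthesis did not pass under mock (adjusted p = 0.819), nor did the COPII list (0.554), the COPI and Golgi list (0.138) or the ATF4 and CHOP list (0.586). G2/M and mitosis (0.067) passed without HMLE-Twist mock replicate 3 (0.0308), within 0.0308 to 0.121. Hypoxia and glycolysis (0.0747) passed without HMLE-Twist mock replicate 1 (0.0336), within 0.0336 to 0.438. In all, 8719 genes differed under mock, 4298 higher and 4421 lower in HMLE-Twist, and 1174 and 2006 of these by at least 2-fold. Size factors set within each table instead of over all libraries gave 8904 genes, 5146 higher and 3758 lower. They moved the median difference of all genes by 0.138.

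Under salinomycin the same markers still parted the lines, with TWIST1 again set by how HMLE-Twist was made. TWIST1 was higher in HMLE-Twist by 8.16 ± 0.26, COL6A2 by 8.04 ± 0.26, COL6A1 by 7.45 ± 0.22, the aminopeptidase ANPEP by 7.35 ± 0.12, COL3A1 by 7.20 ± 0.30 and COL1A1 by 7.20 ± 0.17. KRT5 (-9.21 ± 0.19), KRT6A (-9.18 ± 0.23), KRT17 (-8.57 ± 0.12), SPINT2 (-8.42 ± 0.09), KRT14 (-8.39 ± 0.16) and COL17A1 (-8.37 ± 0.14) were lower. VIM (5.25 ± 0.22), ZEB1 (4.19 ± 0.13), CDH2 (2.47 ± 0.10) and FN1 (2.43 ± 0.09) were higher, and CDH1 (-7.42 ± 0.08), ESRP1 (-5.60 ± 0.08) and HSPA5 (-1.04 ± 0.11) lower. HMGCS1, higher in HMLE-Twist under mock, was lower there under salinomycin (-1.78 ± 0.19, adjusted p = 5.08e-06). DDIT3 no longer passed (0.46 ± 0.35, adjusted p = 0.266). In all, 7535 genes differed, 3732 higher and 3803 lower, and 840 and 1423 of these by at least 2-fold. With size factors set within each table the count was 7944, 4819 higher and 3125 lower, with a shift of 0.132 in the median of all genes. Of the genes that differed under both treatments 6524 kept their direction and 104 had the opposite one, and across genes the differences under mock and under salinomycin had a Pearson r of 0.940.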

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

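Each result in this part stands out because the lines responded differently to salinomycin by a test of the difference itself, the response of HMLE-Twist minus that of HMLE-pBp. The tests of scaling and of single libraries for the cholesterol genes and the splits that part pairs were chosen after the result was seen. The response differed for 1622 genes. Of 100 splits of the 12 libraries into groups of the same sizes, 2 gave as many genes, the real one included. Such splits also move the response that the lines share into the spread within groups. They therefore test for no response at all, and cannot exclude chance for a count of differences. The highest other count was 3581, in the split with the treatment labels of 1 line exchanged, which tests the sum of the responses in place of their difference. Without that split the highest other count was 892. Of the 32 splits that part all pairs of the same number in both lines, 2 gave as many genes, the real one and the exchanged one, and the highest other count was 650. That share is not under 0.05, so against these splits chance is not excluded.

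The medians of the difference over gene lists were -1.62 for cholesterol biosynthesis, -0.73 for fatty acid synthesis, 0.90 for NF-kB targets, 0.45 for breast stem and progenitor markers, -0.41 for hypoxia and glycolysis, 0.36 for Wnt targets, 0.29 for Golgi glycosylation, 0.26 for ion transport and -0.25 for G2/M and mitosis. All 9 lists lost the call with an estimated correlation, at an adjusted p from 0.0621 for cholesterol biosynthesis to 0.669 for G2/M and mitosis. For the number of such lists, 9, chance cannot be excluded: 50 of 100 splits gave as many, and the highest other split gave 16.

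Sterol and fatty acid genes responded lower in HMLE-Twist: ACSS2 (-3.3), HMGCS1 (-2.98), INSIG1 (-2.66), ACAT2 (-2.51), IDI1 (-2.41), FADS2 (-1.79) and SCD (-1.69). The glycolysis genes ALDOC (-2.27) and PFKFB4 (-0.95), the hypoxia gene BNIP3 (-0.99), and the cell division genes CCNB2 (-0.6), CDK1 (-0.56) and NUSAP1 (-0.51) did so too. ESRP1 (-0.59) was near 0 in HMLE-Twist, so that its value restates its rise in HMLE-pBp. The glycosylation enzymes B4GALT5 (1.02), GALNT3 (0.96) and ST3GAL1 (0.86) responded higher in HMLE-Twist. RCN3 (2.94) did too, but it lay at 0.0267 and 0.266 FPKM in HMLE-pBp, where the added 1 understates a rise. So did the cytokine and survival genes CXCL1 (2.43), CXCL8 (2.09), IER3 (2.41) and BIRC3 (1.38), and the signalling genes MYC (2.11), DUSP4 (2.02) and CCND1 (1.22). The transporters SLCO4A1 (2.2), SLC6A6 (1.7), KCNN4 (1.15) and SLC12A7 (0.98), the surface markers PROCR (0.9) and CD44 (0.76), and FN1 (0.74) were higher as well. Some of these calls ended with 1 library left out, as the adjusted p shows. Without HMLE-Twist salinomycin replicate 1 it was 0.0784 for CXCL1 (0.00208 to 0.0784 over the alternatives), 0.0965 for BIRC3 (0.000265 to 0.0965) and 0.0546 for CD44 (0.00971 to 0.0546). Without HMLE-Twist salinomycin replicate 3 it was 0.0782 for CCND1 (0.00613 to 0.0782), 0.051 for CCNB2 (0.00476 to 0.051) and 0.0786 for NUSAP1 (0.00322 to 0.0786). Without HMLE-pBp mock replicate 3 it was 0.0935 for CDK1 (0.00614 to 0.0935) and 0.0606 for PROCR (0.00102 to 0.0606).

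The opposite response of the cholesterol genes was weighed against technical explanations. Separate scaling of the deposited tables would shift all genes alike. Size factors set within each table moved the median difference of all genes by -0.006, against the list's -1.62, which argues against scaling. Of 10000 random lists of as many genes, 0 had a median as low, and their lowest was -0.29. These draws add no test of scaling. Joint size factors had already put the median of all genes at -0.0019, and the list was singled out for its low median. A single library is argued against as well, since the median closest to 0 with 1 library left out was -1.6, without HMLE-Twist mock replicate 3. Of 10000 random lists matched on length and expression level, 0 had a median as low, and their lowest was -0.33, which argues against length and level. Random draws do not keep the correlation between genes of a pathway, and the list lost its call with an estimated correlation. A difference between the lines in how sterol synthesis responds to salinomycin may therefore be a biological one, as a hypothesis found and tested on the same data.

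For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In HMLE-Twist 3130 genes changed and the highest other split gave 0 (1 of 10 splits as large, the real one). In HMLE-pBp it was 2227 genes against 1 (1 of 10), between the lines under mock 8719 against 0 (1 of 10) and under salinomycin 7535 against 0 (1 of 10). For lists the counts were 15 against 14 in HMLE-Twist (1 of 10), 14 against 14 in HMLE-pBp (2 of 10) and 9 against 13 between the lines under mock (5 of 10). Of the splits that part all pairs of the same number, 4 in each line, the highest other gave 0 genes in HMLE-Twist and 1 in HMLE-pBp.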

How the results depend on the processing

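The settings voom, size factors within each table, reference length, the block within each line and keeping unsettled genes were chosen after the data were seen. Counts are given in the order HMLE-Twist response, HMLE-pBp response, difference of responses, lines under mock, lines under salinomycin. Within 1.5 times the reported count lay 24 of 28, 20 of 28, 16 of 27, 25 of 27 and 25 of 27 alternatives. With a log2 fold change of at least 1 the counts were 231, 143, 250, 3180 and 2263, and with an adjusted p under 0.01 the first 3 were 1804, 895 and 493, by construction. Genes within 5% of the reference length gave 2001, 1425, 1070, 5536 and 4815, from fewer genes tested. The replicate block gave 3951 and 3460 for HMLE-pBp and the difference, and 9436 and 8390 between the lines. The block within each line gave 4790, 4315 and 3851 for the first 3, and the cause was not tested. Between the lines that fit compares the fitted levels of replicate 1 alone. Its 8337 and 7072 are therefore not counts of the same comparisons. Voom gave 3247, 2210, 1321, 8683 and 7476, of which 3046, 2077, 1258, 8626 and 7410 were shared. Keeping genes with unsettled reads gave 3253, 2339, 1657, 8913 and 7707.

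With 1 library left out, which leaves 2 in a group, the counts ran from 2184 (without HMLE-Twist salinomycin replicate 3) to 3438, from 1114 (without HMLE-pBp mock replicate 3) to 3128 (without HMLE-Twist mock replicate 1), from 772 (without HMLE-pBp mock replicate 3) to 2384 (without HMLE-Twist mock replicate 3), from 7998 to 8790 and from 6773 to 8053. The cause of the rises was not tested. Called lists ran from 14 to 17, 11 to 15, 8 to 12 and, under mock, 8 to 10. With an estimated correlation the called lists were 0, 0, 0 and 1, and fry called 22 between the lines under mock. The cause was not tested. Of 202 results on named genes, 202 kept their side of the threshold with the replicate block, 197 with a pseudocount of 0.1, 197 rescaled to TPM and 172 in every fit with 1 library left out.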

Other observations

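The genes of the next paragraph were chosen after their values were seen, as were the small nucleolar RNA genes and the test of depth for the replicate 3 libraries.

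Single genes of amino acid transport and of the lysosome, and the death receptor TNFRSF10B, responded differently in the lines, while the lists that hold them did not pass for the difference. The adjusted p was 0.773 for ATF4 and CHOP targets, 0.977 for p53 targets and 0.115 for lysosome and autophagy. With quantile normalization the last was 0.0408 and without HMLE-pBp salinomycin replicate 1 it was 0.0441 (0.0408 to 0.414 over the camera alternatives). ATF4 and CHOP targets passed without HMLE-Twist mock replicate 2 (0.0452, within 0.0452 to 0.998). SLC7A5 and SLC3A2, the chains of a large neutral amino acid transporter, rose in HMLE-Twist by 1.23 ± 0.21 and 0.84 ± 0.16 (SE, n = 3 per group) and did not pass in HMLE-pBp (-0.44 ± 0.21, adjusted p = 0.165, and -0.49 ± 0.16, adjusted p = 0.053). Their responses differed by 1.68 ± 0.30 (adjusted p = 0.00547) and 1.34 ± 0.23 (adjusted p = 0.0042). Under mock both were lower in HMLE-Twist, SLC7A5 at -5.50 ± 0.21 and SLC3A2 at -4.12 ± 0.16. The lysosomal protease CTSB rose by 0.80 ± 0.09 in HMLE-Twist and fell by 0.33 ± 0.09 in HMLE-pBp (adjusted p = 0.0245), a difference of 1.14 ± 0.13 (adjusted p = 0.000395), and CTSL differed by 1.30 ± 0.19 (adjusted p = 0.00186). The autophagy gene WIPI1 rose in both lines, by 1.44 ± 0.12 and 1.54 ± 0.12, and its difference did not pass (-0.09 ± 0.17, adjusted p = 0.734). TNFRSF10B, a death receptor, rose by 0.78 ± 0.08 in HMLE-Twist and fell by 0.33 ± 0.08 in HMLE-pBp, a difference of 1.1 ± 0.11 (adjusted p = 0.000162). Of common reference genes, ACTB fell by 0.51 ± 0.08 in HMLE-Twist and did not pass in HMLE-pBp (0.14 ± 0.08), and YWHAZ fell by 0.30 ± 0.10 and rose by 0.33 ± 0.10. The interferon-stimulated gene IFIT1 fell in both, by 1.15 ± 0.12 and 0.46 ± 0.12.

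Small nucleolar RNA genes tended lower after salinomycin in HMLE-pBp: 129 of 147 had a log2 fold change below 0, with a median of -0.66. As lower 12 passed the threshold, a share no higher than the 1102 of 11882 over all genes tested. Their share of reads was 0.0114%, 0.0137% and 0.0177% in the HMLE-pBp mock libraries. After salinomycin it was 0.00542%, 0.007% and 0.0125%, so the groups overlapped. In HMLE-Twist their median was 0.13, but under mock 112 of the 147 were already lower there (median -1.55). The added 1 therefore leaves less room for a fall in HMLE-Twist. A single library is argued against, since the median closest to 0 with 1 library left out was -0.41, without HMLE-pBp salinomycin replicate 1. Short gene length stays open: SNHG genes of at least 500 bp, which host such RNAs, had a median of -0.46, which short length alone would not give, but 63 other genes under 200 bp had a median of -0.47. Loss of short fragments and a biological fall of the transcripts read at these genes may both add to the pattern and cannot be told apart for these 147 genes. The libraries were made for mRNA. Whether these few reads come from the small RNAs themselves or from longer transcripts was not tested, so they do not measure the level of the small RNAs.

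The replicate 3 libraries deviated from their group means together in all 4 groups. Correlations of these deviations between groups ran from 0.48 to 0.72 for replicate 3, from 0.21 to 0.54 for replicate 1 and from 0.04 to 0.42 for replicate 2. Library depth stays open. The HMLE-pBp salinomycin replicate 3 library has a size factor of 0.923, between the 0.879 and 0.973 of the other libraries of its group. Its mean correlation with the other 3 was 0.61, which goes against depth for that library alone. In HMLE-Twist mock, HMLE-Twist salinomycin and HMLE-pBp mock replicate 3 was the deepest (size factors 1.32, 1.21 and 1.07). Depth and replicate number cannot be told apart there. Gene length is argued against, since the lowest correlation was 0.41 after a trend on length was removed. A shared day of culture or preparation may be a source, but the labels give none, and no biological explanation was tested.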
